A study of Mus musculus with 31 samples.

How the data were processed

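Bulk RNA sequencing was read as gene counts in 31 mouse libraries, each with its own table. Per the labels, polyA RNA was extracted with the RNeasy Micro kit from CD4+ T cells or from whole spleen, amplified as full-length cDNA with SMART-Seq v4 chemistry, made into Nextera XT libraries and sequenced on an Illumina HiSeq. The deposited tables hold raw counts of reads per gene, as whole numbers that the authors neither scaled nor filtered. The authors' processing notes name HISAT2 2.1.0 for alignment and HTSeq 0.5.4 for counting for all 31 libraries, with genome build mm10 for 21 libraries and mm10 together with GRCm38 for 10. The annotation release is not stated. The tables of the pre-lymphoma and CD4-Cre sets list 55276 gene symbols and end in the reads that were not assigned to a gene. The tables of the CD4-CreERT2 set are laid out differently and list 49315 Ensembl genes with their coordinates. Of these, 48970 carry a symbol, and 477 share one with another gene or have none. The 48211 symbols in both kinds of table were used wherever sets were compared.

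Counts summed over genes, ran from 12632000 to 37569000 per library, with a median of 29258000. Between 18368 and 34546 genes had at least 1 count. Where the tables report them, entries not assigned to a gene were 27.2% to 31.9% of all in the pre-lymphoma set and 32.7% to 46.0% in the CD4-Cre set. In these entries a read aligned to several places can count more than once, so they are not shares of reads. Of reads aligned to a single place, 10.9% to 12.8% matched no gene in control libraries of the pre-lymphoma set. This share was 8.74% to 9.82% in control/fusion and 7.28% to 8.46% in fusion/fusion libraries, so it fell in the order of the groups. Whether it bears on the genes called between these groups was not tested. Amplified reads without molecular identifiers are not independent molecules, so binomial intervals cover counting error only. The strand of the reads is not stated, so counts of overlapping or near-identical genes, such as the haemoglobins and neighbouring V genes, are uncertain.

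Libraries were grouped by the set they were deposited in, tissue, status and genotype label, which gave 11 groups. Each tumor comparison was fitted on the libraries of its own groups, and the 3 groups of the pre-lymphoma set shared 1 fit. A pair of interaction contrasts tested whether the tumor effect differed between CD4+ cells and spleen of the CD4-Cre mice, and between the spleens of both tumor models. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and genes were tested with the quasi-likelihood F test of edgeR 4.0.16, a two-sided test. Adjusted p-values follow Benjamini-Hochberg over all genes tested in a comparison, and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Levels are TMM-scaled CPM, gene counts scaled to a common library size, with the standard deviation (SD) between libraries.

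33 gene lists with 361 genes were written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes, except where the text says otherwise. They cover T cell states, processes, markers of other cell types and signs of library quality. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, adjusted over the lists. An estimated correlation for each list was the alternative. For each comparison the text names Vav1, Myo1f, Cd4, Gata3 and Mki67; for each list, up to 4 members that passed with the largest change among members of mean log2 CPM of at least 1, or otherwise up to 2 members of the highest level; and the 8 highest and 8 lowest genes (6 for the interactions) that passed, of mean log2 CPM of at least 3, whose group ranges do not overlap (a condition not used for the interactions), leaving out gene models, receptor and immunoglobulin segments, pseudogenes, ribosomal protein and sex-linked genes. The text prints a part of these names.

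Usage of T cell receptor V genes was measured as the share of all Trbv counts taken by the most counted Trbv gene of a library, with exact Clopper-Pearson 95% intervals from scipy 1.17.1. Tumor and control libraries were compared by exact two-sided permutation of the labels within sets. Scores of gene lists are the mean log2 CPM over the members in a library. Fold changes of different comparisons were compared across genes by Spearman's rank correlation, without a p-value, since genes are not independent replicates.

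Each count was recomputed with RLE scaling, with scaling that left out immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes, without the filter, with DESeq2 1.42.0, with other groups of the set in or out of the fit, without the libraries that carry the number VM645, and without each library in turn. Mouse numbers are shared by CD4+ cell and spleen libraries of the CD4-Cre set. Across genes, centred values of libraries with the same number correlated at 0.585, 0.495, 0.461, 0.389, 0.446 and 0.479, all above the 0.1 set as the minimum, so the number was tried as a replicate block in the interaction between tissues. The alternatives added after the data were seen were a term for the sex of the mouse, read from Xist and Ddx3y counts, and the removal of both libraries of mouse VM98.

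The fits were tested on simulated counts with the depth of the real libraries and their fitted spread at each expression level. Genes were drawn independently, and the single genes changed had a mean log2 CPM of at least 3. Shifts shared by many genes of a library were not simulated, so recovery and false calls may differ in the real data. Of 100 genes changed 4-fold, the pre-lymphoma comparisons recovered 100 each, the CD4+ cell comparisons 70 (CD4-Cre) and 37 (CD4-CreERT2), the spleen comparisons 42 (CD4-Cre) and 2 (CD4-CreERT2), the interaction between tissues 18 and that between models 3. At most 10 unchanged genes were called in any of them. A cell division list raised 2-fold in these counts was called by camera with the preset correlation in every comparison. With an estimated correlation it was missed in CD4-CreERT2 CD4+ cells (camera, adjusted p = 0.518) and CD4-CreERT2 spleen (0.099), and called in the other comparisons. In those CD4-CreERT2 comparisons a list that fails with an estimated correlation therefore says little. R 4.3.3, the data.table package, version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.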

Results

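The 31 libraries were made from CD4+ T cells or whole spleen of mice, to compare normal cells, a state before lymphoma and tumors in models of peripheral T cell lymphoma. The genotype labels name a conditional Vav1-Myo1f fusion allele, switched on by Cre recombinase under control of Cd4 or by CreERT2, a Cre that acts in the presence of tamoxifen. Vav1 is a guanine nucleotide exchange factor that acts below the T cell receptor, and Myo1f is a class I myosin. The pre-lymphoma set held CD4+ T cells only, with 2 control libraries and 3 libraries in each of a pair of pre-lymphoma groups. One of these groups has a genotype label that joins control and fusion by a slash, and the other a label that names the fusion on both sides. What the slash stands for is not stated, so the groups are called control/fusion and fusion/fusion here. The CD4-Cre set held CD4+ cells of 3 control and 4 tumor mice and spleens of 3 control and 3 tumor mice. The CD4-CreERT2 set held CD4+ cells of 2 control and 2 tumor mice and spleens of 3 control and 3 tumor mice. The number VM645 is carried by a tumor library and by control libraries of the CD4-Cre set. Their genotype labels differ, with the fusion allele in the former and CD4-Cre(WT) in the latter. As labelled they are different mice that share a number, and they were counted so. Whether the number is right was not tested. Depth ran from 12632000 to 29258000 gene counts in the pre-lymphoma set, from 24480000 to 37569000 in the CD4-Cre set and from 24772000 to 36880000 in the CD4-CreERT2 set. The labels do not say whether the libraries of the pre-lymphoma set are separate animals, so their p-values measure the spread between these libraries only. Changes are given as log2 fold changes with their standard error.

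Before lymphoma, CD4+ T cell libraries carried more Myo1f and less Vav1 transcript than control libraries. Myo1f (ENSMUSG00000024300; chromosome 17, 33555707 to 33607764 in GRCm38, plus strand) rose from 76.8 ± 8.65 CPM (gene counts scaled to a common library size) in control (SD, n = 2) to 159 ± 11.4 in control/fusion (n = 3) and 164 ± 19.5 in fusion/fusion cells (n = 3). Vav1 (ENSMUSG00000034116; chromosome 17, 57279100 to 57328031, plus strand) fell from 230 ± 8.56 to 196 ± 9.86 and 164 ± 3.95 CPM. Over both pre-lymphoma groups together, Myo1f changed by 1.08 ± 0.10 (adjusted p = 6.0e-05) and Vav1 by -0.36 ± 0.06 (adjusted p = 0.00086), by edgeR. Counts per gene do not tell fused from normal transcripts, nor those of T cells from those of other cells, whose markers also moved in these libraries. In CD4-Cre controls Myo1f stood at 378 ± 38.5 CPM in whole spleen and 358 ± 84.9 in CD4+ cells, so it is not limited to CD4+ cells. Cd4 itself (ENSMUSG00000023274; chromosome 6, 124864692 to 124888221, minus strand) stood at 1031 ± 60.2, 1016 ± 47.1 and 991 ± 24.4 CPM and did not pass the test (-0.04 ± 0.06).

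**Figure D1:**
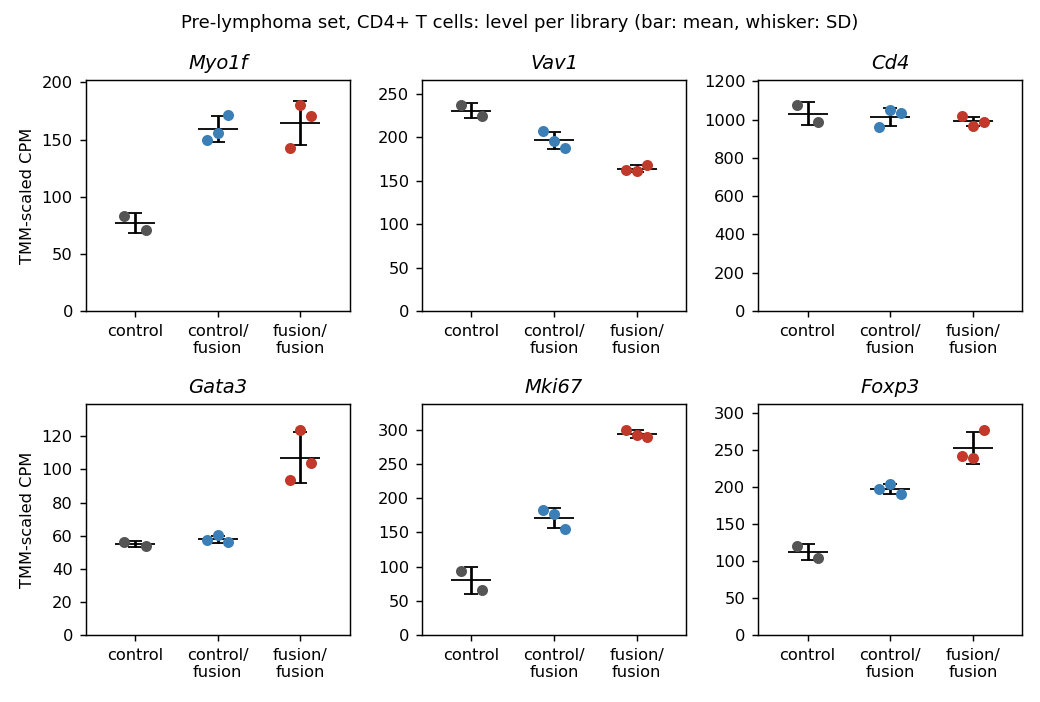
TMM-scaled CPM (gene counts scaled to a common library size) of 6 genes in each CD4+ T cell library of the pre-lymphoma set, with group means (bars) and SD (whiskers), all axes starting at 0. Myo1f reached a similar mean in both pre-lymphoma groups (159 and 164 CPM), whereas Gata3 stood at 57.9 CPM in control/fusion and 107 CPM in fusion/fusion libraries.

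Genes of dividing cells were higher in the pre-lymphoma cells. All 20 cell division genes tested rose, with a median change of 1.63; examples were the spindle genes Nusap1 (1.89 ± 0.12) and Tpx2 (1.82 ± 0.15) and the cyclin Ccnb2 (1.86 ± 0.16). Mki67 (ENSMUSG00000031004; chromosome 7, 135689784 to 135716361, minus strand), a marker of cycling cells, rose by 1.49 ± 0.12. Of 15 DNA replication genes 14 rose, among them Rrm2 (1.62 ± 0.18) and Cdc6 (1.60 ± 0.19), and adjusted over the list alone 14 rose and 1 fell. Of 14 glycolysis genes 9 rose, such as the lactate transporter Slc16a3 (1.01 ± 0.16), and 11 rose adjusted over the list alone. By camera these lists were higher, with adjusted p = 1.8e-15 for cell division, 2.1e-07 for DNA replication and 0.00026 for glycolysis, against adjusted p = 0.382, 0.382 and 0.441 with an estimated correlation. Ribosome biogenesis and MYC target genes went the other way, with 7 of 15 lower and 2 higher (adjusted p = 0.0192; adjusted p = 0.508 with an estimated correlation). The higher ones included Odc1, the first enzyme of polyamine synthesis (1.31 ± 0.11), and the lower ones Ppan (-0.43 ± 0.06).

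Genes of the naive state were lower and genes of effector programs higher, with a median change of 1.70 for T helper 2 genes. All 12 naive and resting T cell genes fell, among them Igfbp4 (-1.57 ± 0.09), the lymph node homing receptor Ccr7 (-1.31 ± 0.07) and the transcription factor Bach2 (-1.17 ± 0.10). Of 18 T cell activation genes 16 rose, such as the costimulatory receptor Tnfrsf9 (1.85 ± 0.14) and the IL-2 receptor chain Il2ra (1.22 ± 0.10), and 1 fell. Of 13 T helper 2 and GATA3 genes 11 rose and 1 fell; examples were the cytokine Il4 (2.19 ± 0.24), the IL-33 receptor Il1rl1 (2.09 ± 0.17) and Il10 (1.97 ± 0.16). Gata3 (ENSMUSG00000015619; chromosome 2, 9857078 to 9890034, minus strand), the transcription factor that directs T helper 2 cells, rose by 0.52 ± 0.10. All 8 regulatory T cell genes rose, among them Itgae (1.66 ± 0.19), Lrrc32 (1.37 ± 0.10) and Ctla4 (1.14 ± 0.07). Camera called the naive list lower and the other lists higher, with adjusted p = 2.6e-10 (naive), 5.1e-08 (activation), 2.1e-07 (T helper 2) and 1.5e-07 (regulatory T cell). With an estimated correlation the adjusted p = 0.258 for each of the 4 lists. Adjusted over the list alone, their counts were the same.

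Further T cell programs rose in part. Of 13 T helper 1 and cytotoxic genes 8 rose and 1 fell: granzyme B (Gzmb, 1.99 ± 0.16) and Klrg1 (1.53 ± 0.16) were higher, while perforin (Prf1, -1.71 ± 0.09) was lower. Of 10 T follicular helper genes 8 rose, among them Pdcd1 and Tox2 (1.44 ± 0.25 and 1.44 ± 0.22), and of 9 inhibitory receptors 8 rose, such as Tigit (1.49 ± 0.20). Of 6 T helper 17 genes 4 rose, including Rora (1.14 ± 0.08). The adjusted p-values were 0.0139, 0.0002, 2.9e-05 and 0.00629 in this order, and with an estimated correlation the adjusted p was 0.382, 0.441, 0.258 and 0.442. Interferon-stimulated genes were mixed, with 9 of 14 higher (Rsad2, 1.22 ± 0.19) and 2 lower (Oas2, -0.81 ± 0.17; adjusted p = 0.0218; adjusted p = 0.606 with an estimated correlation). T cell receptor signalling and T cell identity genes split, with 5 of 17 higher (Cd5, 0.69 ± 0.08) and 3 lower (Cd247, the zeta chain of the receptor complex, -0.81 ± 0.07; list adjusted p = 0.75). NF-kB target genes (5 of 12 higher, 2 lower) and p53 target genes (2 of 7 higher, with Cdkn1a at 1.66 ± 0.32) were not called as lists (adjusted p = 0.369 and 0.234). In all of these lists the counts adjusted over the list alone were the same.

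Markers of other cell types moved in the same libraries, although the cells were selected as CD4+. Of 12 erythroid markers 11 rose, with a median of 1.88 and an example in Slc4a1 (2.26 ± 0.55); the haemoglobin gene Hbb-bs stood at 46.7 ± 27.3 CPM in control, 158.9 ± 119 in control/fusion and 174.6 ± 11.6 in fusion/fusion cells. Within control/fusion it stood at 292 CPM in TA020, the only female library of this set by Xist and Ddx3y counts, and at 65.5 and 119 in TA021 and TA022. Of 20 macrophage and monocyte markers 9 rose, such as Marco (1.77 ± 0.54), and 10 adjusted over the list alone. Dendritic cell markers (6 of 8 higher, 7 adjusted over the list alone; Siglech, 2.25 ± 0.29), plasma cell markers (5 of 7; Sdc1, 1.10 ± 0.17), MHC class II genes (5 of 7) and stromal and endothelial markers (5 of 11 higher, 1 lower, and 7 higher adjusted over the list alone; Kdr, 2.43 ± 0.33) rose as well. Monocyte-attracting chemokines and growth factors rose (6 of 8), among them Ccl8 (2.66 ± 0.35) and Csf1 (1.38 ± 0.17), as did 4 of 10 genes of alternatively activated macrophages, or 5 adjusted over the list alone (Arg1, 3.89 ± 0.82). The adjusted p-values of these 8 lists ran from 0.00012 to 0.0419, and from 0.382 to 0.510 with an estimated correlation. B cell markers were not called as a list, with 3 of 13 lower, or 2 adjusted over the list alone (Fcer2a, -0.53 ± 0.10; list adjusted p = 0.0864). Neutrophil (0 of 10), CD8 T cell (0 of 2) and mitochondrially encoded genes (0 of 10) had no member that passed; their most counted members S100a9, Cd8b1 and mt-Co1 stood at -0.11 ± 0.23, -0.25 ± 0.10 and -0.12 ± 0.15. NK cell markers (2 of 6 higher, 1 lower), megakaryocyte markers (1 of 5 lower) and dissociation and stress genes (2 of 11 higher, 3 lower) were not called either; adjusted over the list alone no megakaryocyte marker was lower and 3 stress genes were higher. Among these uncalled lists the median, mean and test differed in sign for neutrophil, NK cell and megakaryocyte markers.

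Outside the lists, Actg2 (3.75 ± 0.16) and Smtn (3.13 ± 0.13), which encode a smooth muscle actin and an actin-binding protein, were among the largest rises. Ly6c1, a surface protein of several kinds of blood cell, fell by 2.62 on the log2 scale (SE 0.08), and Als2cl fell by 1.76 (SE 0.07). In all, 3343 of 16257 genes were higher and 3075 lower; 1201 and 400 of them changed more than 2-fold. Without control library TA019 the counts were 1794 and 1696, and a single control library is then assumed to vary like the other groups. Camera called 19 lists higher and 2 lower, and none with an estimated correlation.

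The pre-lymphoma groups differed from each other, and several programs were further from control in fusion/fusion cells. Against control, cell division genes had a median change of 1.14 in control/fusion and 2.07 in fusion/fusion cells, with all 20 genes higher in both. The median of T helper 2 genes was 1.16 and 2.16, and that of the naive genes -0.63 and -1.11. The medians of other lists were 0.75 and 0.45 for macrophage, 0.94 and 0.52 for dendritic cell and 0.48 and 0.28 for MHC class II genes, and none of these lists was called in the direct comparison (adjusted p = 0.897, 0.291 and 0.54). Erythroid markers had medians of 1.76 and 1.99, the first of which depended on TA020. Their mean log2 CPM was 4.61 in TA020, 3.0 in TA021 and 3.53 in TA022, and without TA020 the control/fusion median was 0.96, that of macrophage markers 0.45. Compared directly, fusion/fusion cells had 1559 genes higher and 1512 lower than control/fusion cells. Myo1f was not among them (0.04 ± 0.10, adjusted p = 0.80), while Vav1 (-0.26 ± 0.06), Gata3 (0.89 ± 0.09) and Mki67 (0.78 ± 0.11) were.

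**Figure D2:**
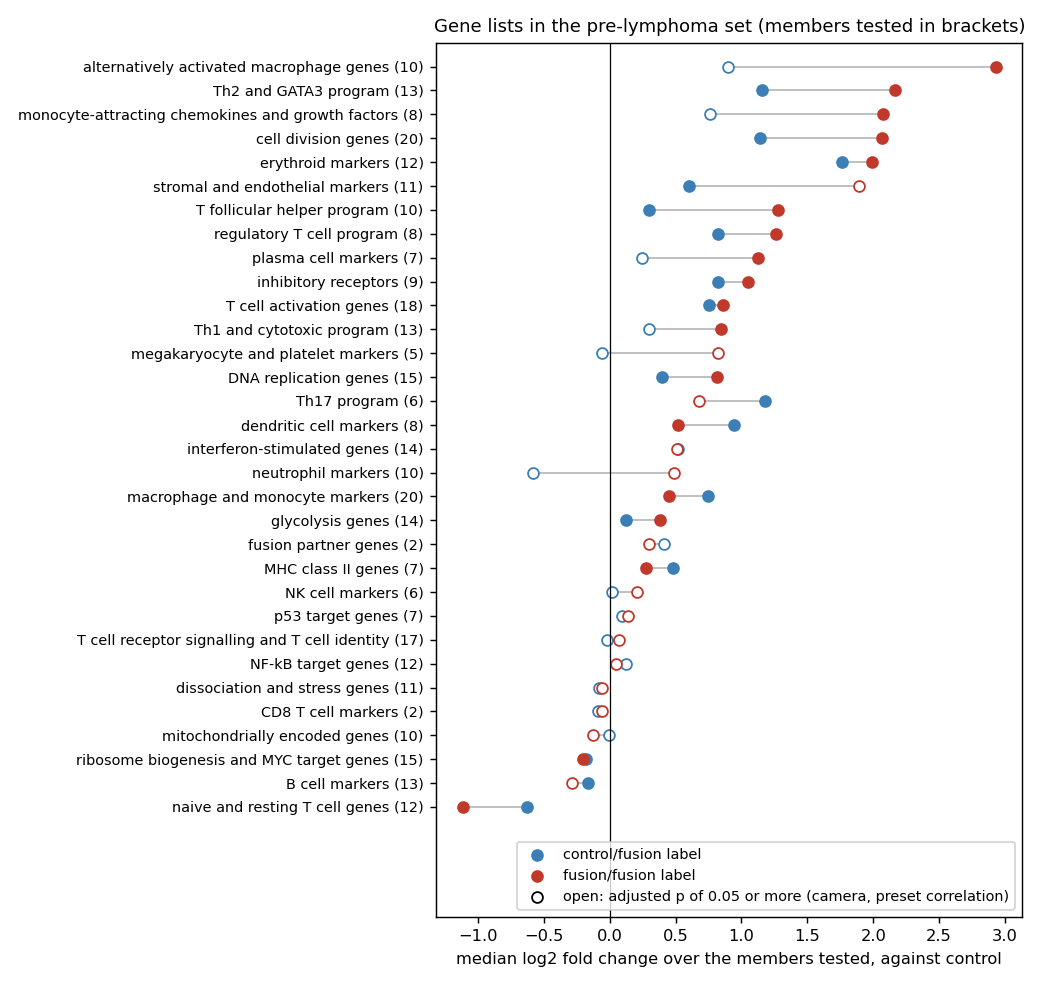
Median log2 fold change against control over the tested members of each gene list, for control/fusion and fusion/fusion libraries; filled points passed camera with a preset correlation, none passed with an estimated correlation, and the sex-linked list is left out. Cell division genes lie at 1.14 and 2.07, macrophage markers at 0.75 and 0.45.

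In this direct comparison, 11 of 13 T helper 2 genes rose, or 12 adjusted over the list alone, led by Il4 (2.06 ± 0.21) and Il1rl1 (1.46 ± 0.15). All 20 cell division genes rose (Birc5, 1.23 ± 0.16), and 10 of 12 naive genes fell, or 11 adjusted over the list alone (Igfbp4, -1.84 ± 0.10). Of 13 T helper 1 and cytotoxic genes 7 rose and 1 fell (8 and 2 adjusted over the list alone), with Gzmb at 2.19 ± 0.14 and Klrg1 at 1.75 ± 0.15. Of 6 T helper 17 genes 2 fell, among them Ccr6 (-0.71 ± 0.14). Monocyte-attracting factors rose, with Ccl8 at 3.85 ± 0.30 and Csf1 at 2.09 ± 0.16 (5 of 8 higher, 7 adjusted over the list alone). Chil3, a gene of alternatively activated macrophages, rose by 5.07 ± 0.76. Among markers of other cells, plasma cell markers rose (6 of 7; Mzb1, 2.01 ± 0.24), as did neutrophil markers (5 of 10, 8 adjusted over the list alone; Ngp, 1.22 ± 0.31). None of 12 erythroid markers passed the test in this comparison; Hbb-bs stood at 0.14 ± 0.45 and Hba-a1 at 0.25 ± 0.44. Without TA020 the median of the erythroid markers in this comparison was 1.02 instead of 0.24, and 5 of them rose (list adjusted p = 0.00033 by camera, with the preset correlation only). Camera gave adjusted p = 2.9e-09 for the T helper 2 list, 3.4e-15 for cell division, 7.4e-11 for the naive list, 0.00314 for T helper 1, 0.0386 for T helper 17, 5.5e-06 for the chemokines, 5.9e-07 for plasma cell and 0.00098 for neutrophil markers. With an estimated correlation the adjusted p was 0.301 to 0.633 over these lists. Against control, 1885 genes were higher and 1414 lower in control/fusion cells, and 3863 and 3573 in fusion/fusion cells. Without control TA019 the control/fusion counts were 522 and 330, and the lower genes were 904 without control TA018 and 922 without control/fusion library TA020. The direct comparison gave 813 and 769 without TA024, 994 and 851 without TA025, 958 and 981 without TA021, and 1024 and 1118 without TA022.

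In CD4+ cells of CD4-Cre tumors, few genes passed the test, and those that fell included markers of macrophages and B cells. The iron exporter gene Slc40a1 fell from 905 ± 315 CPM in control (SD, n = 3) to 17.4 ± 10.3 in tumor cells (n = 4), a change of -5.70 ± 0.56. The macrophage scavenger receptor Cd163 changed by -5.19 ± 0.48, the B cell complement receptor Cr2 by -4.43 ± 0.52 and the myeloid receptor Clec12a by -3.75 ± 0.47. Txk, a kinase of the T cell receptor pathway, changed by -1.86 ± 0.25. The 3 genes that rose were Cpd (1.74 ± 0.20), H1f0 (1.55 ± 0.19) and A430093F15Rik (2.34 ± 0.16), the last named after its value was seen. Altogether 3 genes were higher and 25 lower of 17841 (edgeR), 2699 genes had an unadjusted p under 0.05, and DESeq2 called 651 higher and 620 lower. By Xist and Ddx3y counts, controls VM211 and VM216 and tumor VM388 were male and the other CD4+ libraries of this set female. Sex and status were thus partly mixed. With a term for sex, 3 genes were higher and 12 lower, of which 1 and 11 were among those called without it. Cpd, H1f0, Txk and Clec12a then did not pass (edgeR, adjusted p = 0.0909, 0.118, 0.0909 and 0.0909), while Slc40a1, Cd163 and Cr2 did.

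As lists, the genes of cycling cells, glycolysis and T helper 2 cells were higher in these tumor cells. The median change was 1.19 for cell division genes (adjusted p = 5.9e-13), 1.08 for glycolysis genes (1.9e-10) and 2.02 for T helper 2 genes (6.6e-09), against adjusted p = 0.444, 0.444 and 0.343 with an estimated correlation. No member passed over all genes; adjusted over the list alone, 18 of 20 cell division, 11 of 14 glycolysis and 10 of 13 T helper 2 genes rose. Gata3 stood at 116 ± 18.3 CPM in control and 232 ± 80.5 in tumor cells and Mki67 at 48.7 ± 14.9 and 120 ± 32.6, neither of which passed the test (adjusted p = 0.19 and 0.11). DNA replication, activation, T cell receptor and regulatory T cell lists were also higher, with medians of 0.63, 0.83, 0.34 and 1.39 (adjusted p = 0.444, 0.444, 0.343 and 0.444 with an estimated correlation). The naive list was lower, with a median of -0.81 and 5 of 12 genes lower adjusted over the list alone (adjusted p = 0.444 with an estimated correlation). Markers of other cells were lower too, with medians of -1.04 for macrophage, -2.82 for dendritic cell, -0.94 for B cell and -1.28 for MHC class II genes, all at adjusted p = 0.444 with an estimated correlation. Dissociation and stress genes, a sign of how cells were handled, were lower in the same libraries (median -0.93, adjusted p = 0.00417; adjusted p = 0.444 with an estimated correlation), with a mean log2 CPM of 6.99, 6.80 and 6.05 in control and of 5.25, 5.66, 5.59 and 6.11 in tumor cells. For neutrophil markers the test called the list lower (adjusted p = 0.0374; adjusted p = 0.636 with an estimated correlation) while the median was 0.16. Of the 19 lists called, 7 were higher and 12 lower, with adjusted p-values up to 0.0374; with an estimated correlation none was called, with adjusted p-values from 0.343 to 0.636.

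Vav1 and Myo1f were not among the genes that passed in tumor CD4+ cells (-0.15 ± 0.24 and -0.21 ± 0.38). Myo1f already stood at 358 ± 84.9 CPM in the CD4-Cre controls and at 316 ± 140 in the tumors. The number of genes depended on single libraries. Without VM98, whose CD4+ library detected 34546 genes against 21702 to 22369 in the other tumor libraries, 250 genes were higher and 329 lower, and all 28 genes were among them. Then 9 glycolysis genes rose, 5 naive and 5 macrophage genes fell, and 4 cell division and 4 regulatory T cell genes rose over all genes; Mki67 passed at 1.40 (adjusted p = 0.0423). Without control VM216, without control VM645, or without the tumor and control libraries that carry the number VM645, no gene passed; the higher and lower counts were 1 and 4 without control VM211, 2 and 10 without tumor VM388, and 16 and 64 without tumor VM645.

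In CD4+ cells of CD4-CreERT2 tumors no gene passed the test of edgeR, 896 of 17341 had an unadjusted p under 0.05, and DESeq2 called 229 higher and 42 lower. Most of the lists that differed were those of other cell types. Macrophage markers (median 2.50, adjusted p = 2.1e-18), erythroid markers (3.26, 9.2e-14) and neutrophil markers (5.49, 2.7e-08) were higher, and B cell (-1.81, 1.2e-11), mitochondrially encoded (-1.07, 2.8e-10) and plasma cell genes (-1.31, 2.7e-06) lower. Of the 14 lists called, none was called with an estimated correlation (adjusted p of at least 0.511). In simulated data of this design that alternative also missed a list raised 2-fold (camera, adjusted p = 0.518). Adjusted over the list alone, 9 of 20 macrophage, 10 of 12 erythroid and 9 of 12 neutrophil markers rose and 5 of 7 plasma cell genes fell. The neutrophil markers stood apart in 1 tumor, with a mean log2 CPM of 7.40 in VM231 and 1.76 in VM236 against 1.44 and 1.02 in control, and S100a9 at 669 and 21 CPM in these tumors; without VM231 the list median was 1.12 (adjusted p = 0.0142; adjusted p = 0.604 with an estimated correlation). Macrophage markers were at 6.12 and 6.61 against 3.63 and 4.70. The T helper 2 list (median 0.09, adjusted p = 0.352) and the cell division list (adjusted p = 0.518) were not called, and Gata3 stood at 92.7 ± 6.47 CPM in control (n = 2) and 93.7 ± 26.6 in tumor cells (n = 2). Myo1f stood at 204 ± 16.5 and 371 ± 142 CPM and did not pass (0.87 ± 0.35). The neutrophil marker Ngp (6.40 ± 2.21) and the erythroid marker Hba-a1 (3.43 ± 0.38) did not pass either. Without tumor VM236, 1902 genes were higher and 1352 lower, and without tumor VM231 265 and 109, the remaining tumor library being assumed to vary like the other group. All controls of this set and VM236 were female by Xist and Ddx3y counts and VM231 was male, so sex and status are partly mixed here and in its spleens.

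In the spleens of CD4-Cre tumor mice, genes of dividing cells and T helper 2 cells were higher as lists and markers of NK and B cells lower, while no single gene passed. The median change was 1.82 for cell division, 1.19 for DNA replication, 0.84 for glycolysis and 1.42 for T helper 2 genes (adjusted p = 5.8e-09, 2.1e-08, 1.2e-06 and 3.8e-06). With an estimated correlation the adjusted p was 0.571 for each of them and 0.571 or more for all 14 lists called. Other splits of these libraries called a median of 17 lists, so the number of lists does not set the tumor spleens apart. Adjusted over the list alone, 13 of 15 DNA replication genes and 5 of 11 T helper 2 genes rose. NK cell markers had a median of -2.06, B cell markers of -0.74, naive T cell genes of -0.41 and dissociation and stress genes of -1.38 (adjusted p = 1.3e-05, 8.9e-05, 0.00067 and 4.6e-05), with 4 of 6 NK cell markers lower adjusted over the list alone; the adjusted p was 0.571 for these 4 lists with an estimated correlation. Among single genes that did not pass, Gata3 stood at 1.13 ± 0.24, Mki67 at 1.98 ± 0.61, Vav1 at 0.65 ± 0.20, Myo1f at 0.27 ± 0.45 and the NK cell receptor Klrd1 at -2.1 ± 0.50. The tumor spleens differed in Mki67, with 51.0 CPM in VM58, within the controls (26.7 to 57.3), against 233 in VM388 and 273 in VM98. No gene of 17050 passed in edgeR (smallest adjusted p = 0.207), 2373 had an unadjusted p under 0.05, and DESeq2 called 417 higher and 317 lower. Without VM58, 1 gene was higher and 1 lower, and without VM98, 197 were higher and 411 lower; then 10 neutrophil markers fell (median -6.08), all 6 NK cell markers fell (-2.89) and 5 activation genes rose.

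**Figure D3:**
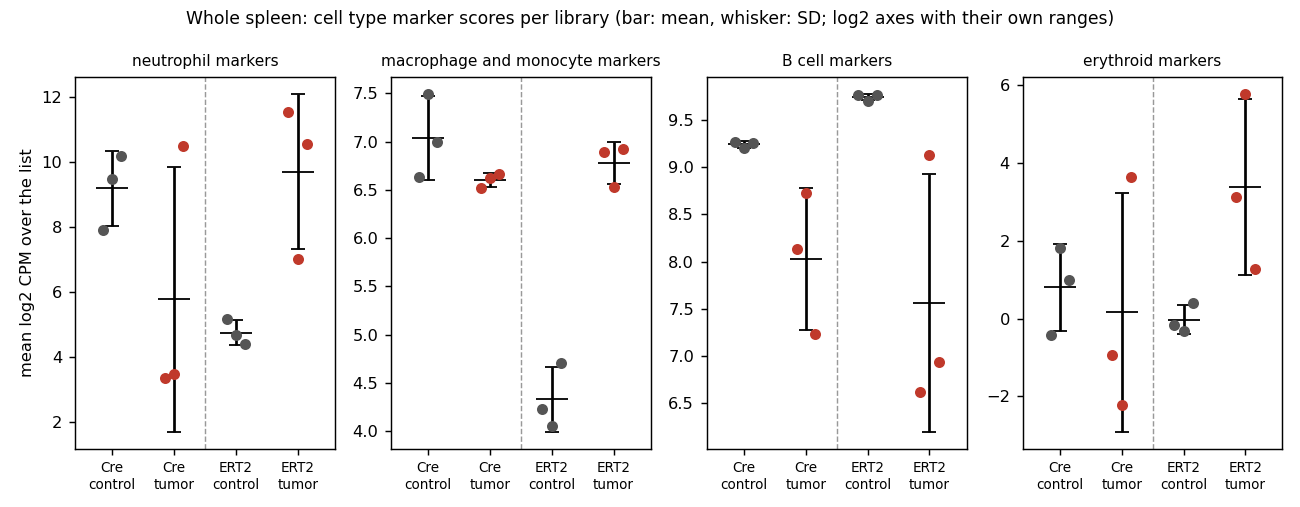
Mean log2 CPM over the markers of 4 cell types in each spleen library of the CD4-Cre (Cre) and CD4-CreERT2 (ERT2) sets, with group means (bars) and SD (whiskers); each log2 axis has its own range. Neutrophil markers stand at 9.19 in CD4-Cre controls and 4.74 in CD4-CreERT2 controls, and the tumor mice of both sets are spread widely.

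In the spleens of CD4-CreERT2 tumor mice, markers of myeloid and erythroid cells were higher as lists and B cell markers lower. Neutrophil markers had a median change of 6.68, erythroid markers of 5.10, alternatively activated macrophage genes of 4.58 and macrophage markers of 2.94 (adjusted p = 4.2e-10, 2.1e-06, 6.7e-06 and 2.1e-13). The adjusted p was 0.641, 0.641, 0.619 and 0.173 with an estimated correlation, and 0.173 or more for all 13 lists called. That alternative also missed a list raised 2-fold in simulated data of this design (camera, adjusted p = 0.099). Adjusted over the list alone, 12 of 12 neutrophil, 18 of 20 macrophage, 7 of 11 erythroid and 7 of 9 alternatively activated macrophage genes rose. Cell division genes (2.15, 16 of 20 higher adjusted over the list alone) and interferon-stimulated genes (1.77, 8 of 14) were higher as well, and B cell markers (-1.55) and naive T cell genes (-1.17) lower (each with adjusted p = 0.641 with an estimated correlation). The mean score of mitochondrially encoded genes, a list of library quality, differed by -1.02 in these spleens and by -0.914 in those of the CD4-Cre set. It was above the control mean in 0 of 6 tumors over both sets (exact permutation p = 0.015, adjusted p = 0.099). The CD4-CreERT2 tumor spleens stood apart from each other. Mki67 was at 14.1 CPM in VM236, below the controls (27.4 to 38.9), and at 158 and 221 in VM231 and VM294, and the mean log2 CPM of erythroid markers was 5.77, 3.13 and 1.27 in VM236, VM231 and VM294. The VM294 library detected 18368 genes against 22574 to 24162 in the other spleens of this set, with the plasma cell gene Jchain at 66290 CPM (2030 to 6298 in the others) and the T cell gene Cd3e at 27.3 (111 to 136), which were named after their values were seen. Among single genes that did not pass, the neutrophil granule gene Ngp stood at 7.26 ± 1.53, the haemoglobin gene Hba-a1 at 5.76 ± 0.92, the macrophage mannose receptor Mrc1 at 2.96 ± 0.53, Myo1f at 1.16 ± 0.64 and Vav1 at -0.13 ± 0.52. No gene of 16163 passed in edgeR (smallest adjusted p = 0.103), 3241 had an unadjusted p under 0.05, and DESeq2 called 1330 higher and 488 lower. In simulated data of this design 2 of 100 genes changed 4-fold were recovered. Without VM236, the only female of the tumor mice, 704 genes were higher and 187 lower, among them 16 cell division and 11 neutrophil genes that rose.

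The tumor effect on spleen, taken against the controls of each set, differed between the models in 8 genes. The sets were deposited separately, and differences between them cancel only where they act alike on control and tumor spleens. Control spleens already stood apart between the sets for Il1b, Lyz1 and Dusp1, so model and set cannot be told apart. Il1b, an inflammatory cytokine, stood at 328 ± 62.2 CPM in control and 24.6 ± 14.9 in tumor spleens of CD4-Cre mice, and at 33.4 ± 1.62 and 48.2 ± 7.34 in CD4-CreERT2 mice (SD, n = 3 each). The lysozyme gene Lyz1 was at 97.9 ± 40.5 and 18 ± 4.91 CPM in the former and 13.2 ± 0.554 and 102 ± 51.8 in the latter, and the stress-response phosphatase Dusp1 at 326 ± 72.1 and 61.6 ± 29.3 against 72.7 ± 17.0 and 291 ± 82. The CD4-Cre minus CD4-CreERT2 difference was -4.27 ± 0.55 for Il1b, -5.39 ± 0.64 for Lyz1 and -4.40 ± 0.62 for Dusp1. It also passed for Steap4 (-9.30), Gm6517 (-8.50), Arg2 (-6.39), Ifit1bl2 (-6.32) and Clec1b (-6.31), which were named after their values were seen. These 8 of 17784 genes had adjusted p-values of 0.0136 or, for Dusp1, 0.0259, and no gene was higher; DESeq2 called 356 higher and 780 lower. Among the lists, macrophage markers differed by a median of -3.22 (adjusted p = 7.5e-13; 0.0443 with an estimated correlation; 18 of 20 lower adjusted over the list alone). Neutrophil markers differed by -6.44 (adjusted p = 4.8e-10; adjusted p = 0.657 with an estimated correlation), and regulatory T cell genes by 1.63 (0.0139; 0.748 with an estimated correlation). Erythroid (-3.22, adjusted p = 0.00219), megakaryocyte (-4.35, 0.0119) and dissociation and stress genes (-1.55, 0.0119) were called as well, against 0.748, 0.697 and 0.748 with an estimated correlation. Other splits of these libraries called a median of 11 lists, as many as the real one. Vav1 and Myo1f did not pass (0.78 ± 0.54 and -0.89 ± 0.79). Without tumor VM388, or without any of the 3 CD4-CreERT2 controls, no gene passed, and 1 was lower without control VM216 or tumor VM58. The higher and lower counts were 628 and 755 without VM231, 114 and 571 without VM98, 9 and 71 without VM236, and 3 and 15 without VM294; with a term for sex none passed.

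The tumor effect in the CD4-Cre mice was also compared between CD4+ cells and spleen, to ask which changes belonged to the sorted cells. No gene of 19503 passed in edgeR (smallest adjusted p = 0.196), 1429 had an unadjusted p under 0.05, and DESeq2 called 27 higher and 24 lower. Relative to spleen, the tumor effect in CD4+ cells was lower for macrophage markers (median -0.97, adjusted p = 0.00208), dendritic cell markers (-1.40, 0.0348), ribosome biogenesis and MYC target genes (-0.41, 0.0377) and stromal markers (-1.64, 0.0377). With an estimated correlation the adjusted p was 0.972 for the first 3 lists and 0.485 for the last. Other splits of these libraries called a median of 6 lists, more than the 4 called here. With mouse number as a replicate block, 0 genes passed, with 1777 at an unadjusted p under 0.05, and 11 lists were called, 3 higher and 8 lower. Without 1 library, 7 lists were called without CD4+ cells of VM211, 8 without CD4+ cells of VM216 or the spleens of VM645 or VM58, and 12 without the spleen of VM98.

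In some tumors 1 V gene of the T cell receptor beta locus took a large share of the counts; cells of a clone share their V gene. In CD4+ cells of VM388, Trbv3 took 51.0% of Trbv counts (exact 95% interval 50.3% to 51.8%), and the same gene took 46.5% in its spleen (44.2% to 48.9%). In VM231, Trbv20 took 66.4% in CD4+ cells (65.7% to 67.1%) and 49.1% in spleen (47.0% to 51.3%), beside Trav13-1 with 52.8% of Trav counts in CD4+ cells and 56.2% in spleen. In CD4+ cells of VM388 and of the VM645 tumor the leading Trav gene took 6.30% and 8.39%, against 5.33% to 8.13% in the controls. In VM98, Trav6n-6 led with 14.2% in CD4+ cells and 7.84% in spleen, where leading genes took 5.13% to 10.8% in CD4-Cre controls. In CD4+ cells of VM58 and VM236 the leading Trav gene took 5.97% and 5.45%. The tumor library of VM645 was led by Trbv12-1 with 37.8%, followed by the closely related Trbv12-2 with 30.2%. In VM58, VM98 and VM236 the leading gene took 11.9%, 15.4% and 15.5%, against 10.5% to 15.2% in the 5 controls. Over both sets the leading share was 33.0% ± 22.5 in tumor (SD, n = 6) and 13.1% ± 1.93 in control libraries (n = 5), higher than every control in 5 of 6 tumors, and the difference within sets of 21.9 did not pass (exact two-sided permutation p = 0.0905; the smallest possible is 0.00476). Within the sets the exact permutation p was 0.257 for CD4-Cre (smallest possible 0.0286) and 0.333 for CD4-CreERT2, where 0.333 is the smallest possible. Over both sets, the difference was 9.15 without VM231 and 34.6 without VM236, and the exact permutation p was 0.0167 without VM58 and 0.0381 without VM236, with a highest value of 0.286 among the libraries left out in turn. The effective number of Trav genes was lower in tumors by 13.2 (exact permutation p = 0.0476), the effective number of Trbv genes by 5.38 (p = 0.1) and the leading Trav share was 15.5% against 6.29% (p = 0.271), without adjustment over these 4 measures.

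**Figure D4:**
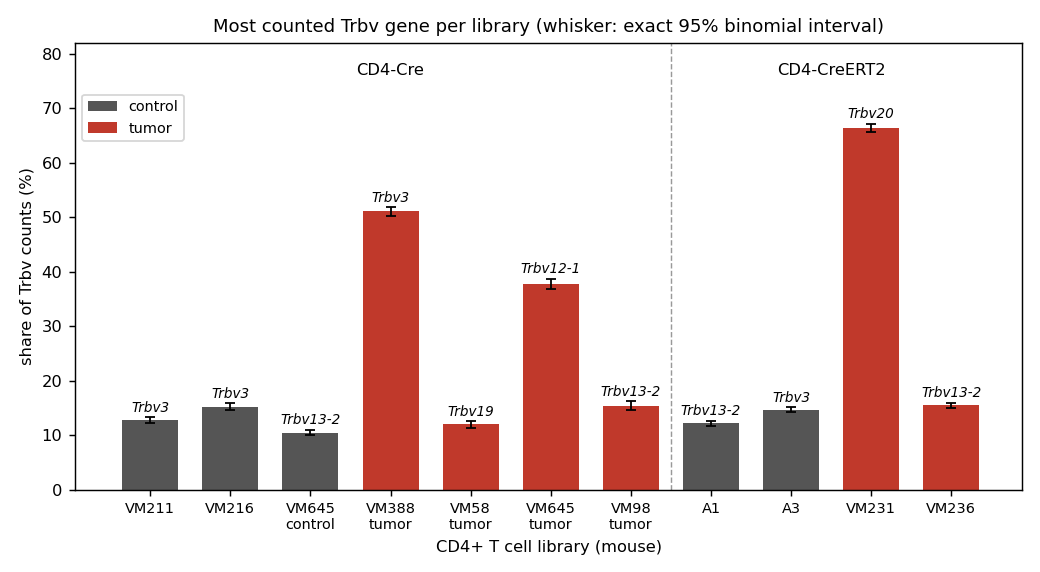
Share of all Trbv counts taken by the most counted Trbv gene in each CD4+ cell library, in percent from 0, with exact 95% binomial intervals (counting error only). VM388, VM645 (tumor) and VM231 stand at 51.0%, 37.8% and 66.4%, the other libraries between 10.5% and 15.5%.

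Fold changes of the tumors showed little likeness between the models. Across 15749 genes tested in CD4+ cells of both, Spearman's correlation of tumor changes was 0.04, and across 14981 genes in spleen -0.04; genes are not independent replicates. Among genes of mean log2 CPM of at least 3 it was 0.10 in CD4+ cells (9077 genes) and -0.17 in spleen (8759 genes). Pre-lymphoma changes and those of CD4-Cre tumor CD4+ cells correlated at 0.16 over 15345 genes and at 0.20 over the 9131 of mean log2 CPM of at least 3, although the pre-lymphoma genotypes carry CD4-CreERT2 and these tumors CD4-Cre, so driver and stage differ together. All 3 genes higher in those tumors were also higher before lymphoma, where chance gives 0.632, 2 of the lower ones were also lower (chance 4.81), and 9 went in opposite directions.

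Sorted libraries held markers of other cells in both tumor sets. The mean log2 CPM of macrophage markers in CD4+ libraries was 6.86 ± 0.33 in control and 5.10 ± 1.51 in tumor cells of the CD4-Cre set, and 4.16 and 6.36 in the CD4-CreERT2 set. B cell markers stood at 6.55 and 4.90 in the former and 8.14 and 5.89 in the latter. In spleen, neutrophil markers stood at 9.19 ± 1.17 in control and 5.77 ± 4.08 in tumor mice of the CD4-Cre set, and at 4.74 ± 0.39 and 9.71 ± 2.39 in the CD4-CreERT2 set. B cell markers in spleen stood at 9.24 and 8.03, and at 9.74 and 7.56.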

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

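The tests of explanations for the markers of other cells, the V genes and mouse VM98, and the counts over other splits of the libraries, were chosen after the results were seen. The interactions between tissues and between models were planned.

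Markers of other cell types stood higher in the pre-lymphoma CD4+ libraries, although the cells were selected as CD4+. A lower share of CD4+ T cells, filled evenly by all other types, would raise their markers alike. The upper quartile of B cell markers was -0.048 and the lower quartile of erythroid markers 1.72, which argues against such an even gain. A lower share filled by particular cell types is not tested by these values. More erythroid cells in the sort remain a candidate explanation for the erythroid part, since 11 of 12 erythroid markers rose and the abundant Hbb-bs stood at 46.7, 158.9 and 174.6 CPM in control, control/fusion and fusion/fusion cells, with 292 in control/fusion library TA020 against 65.5 and 119 in the others. Dividing cells of the added types stay open as carriers of the cell division genes: between the pre-lymphoma groups the highest upper quartile of their marker lists was 1.29 for plasma cell markers, above the lower quartile of 0.812 of the cell division genes, and the erythroid median was 0.24 with TA020 and 1.02 without it, while in control/fusion cells against control the plasma cell (0.24) and neutrophil medians (-0.58) lay below the lower quartile of 1.02 of the cell division genes. A change of the T cells themselves stays open for cell division, and for the other markers it was not tested.

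In some tumor libraries 1 V gene led the Trbv counts. Uneven amplification in a single library may raise 1 gene, but the spleen library of the same mouse had the same leading gene with 46.5% in VM388 and 49.1% in VM231, which argues against it there. In the tumor library of VM645, where no spleen library of the tumor mouse was analysed, the near-identical Trbv12-1 and Trbv12-2 took 37.8% and 30.2%, and reads of 1 gene split between both cannot be told apart from 2 leading genes without the reads. A clonal expansion is a hypothesis that these values leave standing in VM231, where Trav13-1 also took 52.8% of Trav counts, whereas in VM388 it rests on Trbv3 alone, since the leading Trav gene took 6.30% there, within the 5.33% to 8.13% of the controls.

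Without mouse VM98 the CD4-Cre comparisons called more genes. Its CD4+ library detected 34546 genes, apart from the 21702 to 22369 of the other tumor libraries, which could reflect background reads over many genes. Of reads aligned to a single place, 23.67% matched no gene in this library, against 15.68% to 17.49% in the other tumor CD4+ libraries. It also held the male-specific Ddx3y at 3.08 CPM although female by Xist (0.0719 to 0.216 in the other female CD4-Cre libraries). Background from a female mouse cannot supply Ddx3y, so these reads may come from male material. Whether material of several mice was mixed was not tested. In spleen 608 genes were called without the VM98 spleen library, which detected no more genes than the others. Background in the CD4+ library cannot reach the spleen comparison, so it does not account for that part. For the same reason, the spleen count does not test it for the CD4+ cells. Among genes of at least 32 CPM, where a few background reads weigh little, 202 were called in CD4+ cells without VM98 against 14 with it. This argues against background reads as the whole cause in CD4+ cells. A control mouse under a wrong label cannot be told apart from a tumor with little change: between controls (0) and the other tumors (1) VM98 lay at 0.411 in CD4+ cells and at 0.106 in spleen, where the controls lay at -0.0172 to 0.159, while Mki67 in its spleen (273 CPM, controls 26.7 to 57.3), CD8 T cell markers in its CD4+ cells (mean log2 CPM 2.70, controls 4.05 to 4.22) and B cell markers in its spleen (7.23, controls 9.20 to 9.27) lay outside the controls. The leading Trav gene of its CD4+ cells also lay outside the controls, with 14.2% of Trav counts against 5.33% to 8.13%. One split of the same 7 libraries, VM98 with the 3 controls against the other 3 tumors, called 278 genes against 28 for the real one, which points to a structure of the samples.

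Of 44 measures tested in the 1 group of 4 libraries, 2 stood apart: the genes detected in VM98 and the Cd4 level of the VM645 tumor, 367 CPM where the nearest others had 664 to 670. Chance alone sets apart about 1 in 20 such groups for each measure, or about 2 of 44 measures if these were independent. The count of 2 is thus no more than chance gives, but it does not judge either value alone. No other library of any set detected more than 24649 genes.

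The tumor effect differed between CD4+ cells and spleen of the CD4-Cre mice for macrophage (-0.97), dendritic cell (-1.40), ribosome biogenesis and MYC target (-0.41) and stromal and endothelial genes (-1.64), as list medians. Between the models it differed in spleen for 8 genes, by -9.30 for Steap4, -8.50 for Gm6517, -6.39 for Arg2, -6.32 for Ifit1bl2, -6.31 for Clec1b, -5.39 for Lyz1, -4.40 for Dusp1 and -4.27 for Il1b. A difference between the models cannot be told apart here from one between the sets. The lists that differed between the models had medians of -3.22 for macrophage, -6.44 for neutrophil, -2.27 for interferon-stimulated, -3.22 for erythroid, -2.81 for alternatively activated macrophage, -4.35 for megakaryocyte, -1.55 for stress and -1.52 for NK cell genes, and of 1.63 for regulatory T cell, 1.55 for T follicular helper and 0.30 for ribosome biogenesis and MYC target genes. Of the 4 lists between tissues 0, and of the 11 lists between models 1, were called with an estimated correlation.

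Among 35 splits of the CD4-Cre CD4+ libraries, 2 gave as many genes and 2 as many lists as the real split (28 genes, highest other 278; 19 lists, highest other 20), so chance is not excluded for either count. For the interaction between models, 1 of 100 splits, the real one, gave as many as 8 genes (highest other 0), which argues against chance for that count; it was 1 of 12 counts compared over splits after the results were seen, and it was 0 with a term for sex, without VM388 or without any of the 3 CD4-CreERT2 controls. For its lists 54 of 100 gave as many as 11 lists (highest other 21). The other designs have too few splits for a share under 0.05. In CD4-Cre spleen 0 genes and 14 lists were called, with 5 and 22 as the highest others (10 and 7 of 10 splits as large), and in CD4-CreERT2 spleen 0 genes and 13 lists, with 0 and 16 (10 and 3 of 10). Between the pre-lymphoma groups 3071 genes and 14 lists were called, with 1 and 17 as the highest others (1 and 3 of 10 as large). For the interaction between tissues it was 0 genes and 4 lists, with 0 and 10 (20 and 16 of 20). Over the other splits the median number of lists was 10.5 in CD4-Cre CD4+ cells, 17 in CD4-Cre spleen and 7 in CD4-CreERT2 spleen. It was 9 between the pre-lymphoma groups, 6 for the interaction between tissues and 11 for that between models. The real split did not exceed this median in CD4-Cre spleen or in either interaction.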

How the results depend on the processing

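The sex term and the removal of both VM98 libraries were chosen after the data were seen; the other alternatives were planned. Over all alternatives, 5206 of 5406 values of named genes kept their side of the threshold in the pre-lymphoma set. In the tumor sets 536 of 630 did. In these 2 parts 142 and 84 no longer passed, and 58 and 10 newly passed. Direction was compared only where a gene passed in the main fit or the alternative, and there 0 reversed. A change of sign in a gene that passed in neither was not counted. Of list values, 684 of 781 and 618 of 760 kept direction and side of the threshold, 97 and 141 no longer passed, and 1 reversed. The reversed value was that of glycolysis genes in CD4-CreERT2 CD4+ cells, with a median of -0.23 without VM231 and of 1.31 without VM236. With RLE scaling the count of every comparison stayed within 1.5 times its value. In the tumor sets the spread between mice and the few libraries limit what can be called, since 2 to 70 of 100 simulated genes changed 4-fold were recovered. For the values that follow, the cause was not tested, except that fewer libraries or more genes tested are part of some settings.

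By an estimated correlation 0 lists were called in any comparison but the interaction between models, which kept 1. Without the low count filter the genes called higher and lower were 261 and 397 in CD4-Cre CD4+ cells, 89 and 94 in CD4-Cre spleen, 391 and 25 in CD4-CreERT2 spleen, 42 and 13 in CD4-CreERT2 CD4+ cells, 1 and 1 for the interaction between tissues, with 10 lists, and 50 and 396 for that between models. With DESeq2 they were 651 and 620, 417 and 317, 1330 and 488, 229 and 42, 27 and 24, and 356 and 780 in the same order. With all groups of a set in 1 fit they were 24 and 97 in CD4-Cre CD4+ cells, while 1 gene was lower in CD4-Cre spleen and 1 higher in each CD4-CreERT2 tissue. Without the libraries that carry the number VM645, 0 and 0 genes passed in CD4-Cre CD4+ cells. With a term for sex 3 were higher and 12 lower there, of which 1 and 11 passed in the main fit. In the interaction between models 0 passed with that term. Without both libraries of VM98, 1 gene was higher and 1 lower in the interaction between tissues. Scaling without immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes gave 1 higher gene between models. With mouse number as a replicate block, the interaction between tissues called 11 lists against 4, and 0 genes in either direction. Among genes of mean log2 CPM of at least 3, the correlation of spleen changes between models was -0.17.

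Leaving out 1 library in turn, the genes higher and lower ranged from 0 to 250 and 0 to 329 in CD4-Cre CD4+ cells, 0 to 197 and 0 to 411 in CD4-Cre spleen, 0 to 704 and 0 to 187 in CD4-CreERT2 spleen, and 0 to 1902 and 0 to 1352 in CD4-CreERT2 CD4+ cells. They ranged from 1794 to 3280 and 1696 to 3107 for pre-lymphoma against control, 522 to 1935 and 330 to 1518 for control/fusion against control, 2616 to 3928 and 2491 to 3594 for fusion/fusion against control, and 813 to 1500 and 769 to 1667 between both. They stayed at 0 for the interaction between tissues and ranged from 0 to 628 and 0 to 755 for that between models. Lists called ranged from 17 to 22, 13 to 22, 10 to 18, 16 to 21, 20 to 22, 16 to 20, 15 to 19, 13 to 16, 3 to 12 and 4 to 13 in the same order. The difference in the leading V gene share ranged from 9.15 to 34.6. Where 1 library of a group was left, it was assumed to vary like the other groups.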

Other observations

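The tests in this part were chosen after the results were seen. Over the CD4+ libraries of both models together, the mean level of T helper 2 genes stood at 3.28 ± 0.33 log2 CPM in control (SD, n = 3) and 5.16 ± 0.56 in tumor cells (n = 4) of the CD4-Cre set, and at 2.98 ± 0.03 (n = 2) and 3.78 ± 0.98 (n = 2) in the CD4-CreERT2 set. In the pre-lymphoma set it stood at 2.68 ± 0.27 in control, 3.61 ± 0.20 in control/fusion and 4.75 ± 0.08 in fusion/fusion cells. B cell (-1.95) and CD8 T cell markers (-1.47) were below the control mean of their set in all 6 tumors, with an exact permutation p of 0.0095 and 0.105 after adjustment over 33 lists. In spleen, naive T cell genes differed by -1.46, B cell markers by -1.69 and p53 target genes by 0.45, in this direction from the control mean in 6 of 6 tumors each, with an exact permutation p of 0.005, the smallest that the arrangements allow, and 0.055 after adjustment. None of the lists passed in either tissue, but with 33 lists fewer than 4 at the smallest possible p cannot pass, so this says little.

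Genes differed in how much of their fusion/fusion change was present in control/fusion cells. The share was 0.943 ± 0.143 (SE) for Myo1f, 0.88 ± 0.0149 for Ly6c1, 0.515 ± 0.0986 for Vav1, 0.427 ± 0.0546 for Mki67, 0.115 ± 0.0183 for Gzmb, 0.0603 ± 0.0458 for Csf1 and 0.0558 ± 0.0334 for Gata3.

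One hypothesis for the graded changes is that control/fusion libraries are a mixture of control and fusion/fusion cells. A mixture would give all genes 1 share, but those of Myo1f and Gata3 differed by 6.03 standard errors, which argues against it as the whole cause, although these genes were picked after their shares were seen. Over the 680 genes of mean log2 CPM of at least 3 that passed and changed over 2-fold in fusion/fusion cells against control, the share had quartiles of 0.33 and 0.626 and a median of 0.47, with 18 genes above 1 and 16 below 0. What the label with the slash stands for stays open.

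A second hypothesis is that T helper 2 genes may go with tumor status in CD4+ cells of both models. The mean difference within sets was 1.34 (1.88 in CD4-Cre and 0.80 in CD4-CreERT2), with all 6 tumors above the control mean of their set, an exact two-sided permutation p of 0.0048, the smallest of 210 arrangements, and an adjusted p of 0.105, which does not pass and leaves it open. In the CD4-CreERT2 set alone the list was not called (median 0.09, adjusted p = 0.352), and its tumors stood at 3.09 and 4.48 log2 CPM against 2.96 and 3.01 in control, so the difference there rests on 1 tumor.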
